A study of Homo sapiens with 4 samples.

How the data were processed

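Total RNA was profiled on 4 Affymetrix human expression arrays of 54675 probe sets each. All samples were LM2 cells, a derivative of the MDA-MB-231 human breast cancer line that is highly metastatic to lung. Per the labels, 2 arrays came from cells with a short hairpin control vector and 2 from cells with a vector for the microRNA miR-335, with replicates lettered A and B in each group. RNA was isolated with a miRVANA kit, and biotin-labelled cRNA was made from 10 ug of total RNA, per the labels' protocols. The labelling text of control replicate A speaks of standard Affymetrix techniques, while that of the other arrays names a high-yield labelling kit. Whether the lettered replicates were separate cultures is not stated in the labels, so p-values measure only the spread between these arrays, which may be technical.

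The deposited values are linear intensities, 1 signal per probe set and array. The software and method that summarised the probes are not given in the sources used here. The mean signal after trimming 2 percent of the values at each end was 500.1 on every array, so the arrays carry a global scaling to a common mean. Median signals were 117 and 114 on the control arrays and 102 and 106 on the miR-335 arrays. The 3'/5' signal ratio of GAPDH lay between 0.927 and 0.986 and that of ACTB between 1.13 and 1.21. The number of arrays limits the precision of every value.

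Probe sets were named from the platform annotation given with the series matrix. Of the probe sets, 41097 had 1 gene symbol, 1801 had several, 11721 are not named here and 62 were Affymetrix controls. Among those with 1 symbol, 41043 were matched through Entrez identifiers to the table of current gene symbols, 54 were not matched, and 0 symbols needed an update. Probe sets with several symbols name no gene in what follows. No genome coordinates are given, because no build comes with the arrays. The probe sets with 1 symbol covered 19775 genes.

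Signals were transformed as log2(signal + 22.1), the pseudocount being the 20th percentile of all values. Fold changes are on this scale and understate the change of dim genes. Each gene was represented by its probe set with the highest mean, and probe sets under the 40th percentile of all probe set means, a signal of 67.2, were left out. This left 14086 genes and 32768 probe sets. Several probe sets past the filter were held by 6818 genes, of which 31 had called probe sets of opposite direction. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), as a two-sided comparison of the miR-335 with the control arrays without a block, and p-values were adjusted by the Benjamini-Hochberg method. A gene is said to have risen or fallen, or to be called, where its adjusted p was under 0.05. The fit had 9.68 degrees of freedom, 7.68 of them from the prior. Errors of log2 fold changes are standard errors of this fit, and errors of signals are SDs of 2 arrays. As a reference for dim signal, the 95th percentile over the 27 Bacillus control probe sets was 77.6. A second count, the all-pairs count, took genes whose every miR-335 array differed from every control array by at least 1.5 times in the same direction. On simulated data with 200 changed genes among 14086, the fit recovered 31.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 3 false calls among 143. The simulated spread followed an intensity trend, as the fit assumes, so the few false calls do not test that assumption. Far more genes were called in the data, so these shares need not carry over.

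Before the data were examined, 24 gene lists were fixed: listed miR-335 targets, lung metastasis genes, extracellular matrix, matrix proteases and inhibitors, actin and motility, integrins and adhesion, epithelial markers, mesenchymal markers, cell cycle, interferon response, NF-kB and cytokines, hypoxia response, unfolded protein and amino acid stress, cholesterol synthesis, TGF-beta targets, immediate early genes, SOX, FOX and HOX factors, microRNA machinery, receptor kinases and phosphatases, ribosomal proteins, oxidative phosphorylation, and markers of leukocytes and red cells, endothelium and fibroblasts. Lists were tested against all other tested genes with camera at a preset correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation. In tests on simulated data, a list shifted by 0.5 on the log2 scale was called and 0 of the other lists were. Genes were simulated as independent, so this check says nothing about lists whose genes vary together. After the data were seen, 4 lists were added: ribosome biogenesis, tRNA synthetases, ER chaperones and ATF4 targets. Their p-values were adjusted over these 4, and again over all 28 lists. List members that are not named on the array here were not analysed here.

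The genes named were set by a rule: all listed miR-335 targets, the host gene MEST, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, and up to 4 members of each list with the smallest p.

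The alternatives were quantile normalization, median centring, cyclic loess normalization (chosen after seeing the data), no filter and a stricter filter on level, a lower and a higher pseudocount, the replicate letter as a block, eBayes without trend or with a robust fit, a threshold of 0.1, the mean of a gene's probe sets, and leaving out each array. Without an array its group holds a single array, so calls then rest on the spread of the other group and the prior. A planned search for miR-335 seed sites in 3' untranslated regions was not run, because no transcript sequences were used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.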

Results

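The effect of miR-335 on gene expression was measured in LM2 cells, which were derived from the MDA-MB-231 breast cancer line by selection for metastasis to lung. Cells carried either a short hairpin control vector or a vector expressing miR-335, with 2 arrays in each group. Pearson's r across the 14086 tested genes was 0.989 between the control arrays, 0.987 between the miR-335 arrays and 0.972 to 0.973 between groups, where genes are not independent replicates. The median absolute log2 difference was 0.13 and 0.16 within the groups and 0.27 to 0.30 between them. Of 4 bacterial and phage spike-in controls, only bioC differed between groups by more than within them: its signal was 955 and 1158 on the control arrays and 536 and 536 on the miR-335 arrays, 1.96-fold higher in the controls. The array does not measure mature miR-335, so the labels could not be checked on the microRNA itself.

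Cells with the miR-335 vector differed from control cells in the expression of many genes. The listed miR-335 targets SOX4 and MERTK fell by more than 2-fold, ID3 and KISS1 were among the largest rises, and AGR2, the cystatins CST1 and CST4, and ICAM1 among the largest falls. Of the cell cycle and oxidative phosphorylation genes, 22 of 40 and 12 of 20 rose, and 13 of 20 genes of unfolded protein and amino acid stress, 11 of 15 of cholesterol synthesis and 8 of 15 epithelial markers fell. Each of these 5 lists passed its test at the preset correlation but not with an estimated one (adjusted p = 0.367 in camera for each). The estimated correlation rests on 2 arrays per group. In total 3366 of 14086 genes (23.9%) were called, 1645 higher and 1721 lower with miR-335. The median size of a called change was 1.47-fold, and 62 genes rose and 229 fell by at least 2-fold. The arrays of the 2 groups did not overlap for any of the 3366 called genes, nor for 62.6% of all tested genes, where chance gives 33.3%. The count was 1157 with a variance prior that ignores intensity and 2128 without control replicate A. The share of calls that were higher was 48.9%, and it was 71.8% (2592 higher, 1016 lower) after median centring, which moved the median log2 fold change of all tested genes from -0.05 to 0.09.

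Expression of the 6 listed miR-335 targets was compared first, since the study asked what restored miR-335 does to gene expression in metastatic cells. Of these, 5 fell and 1 was not called, and the count was 5 when adjusted over the list alone. This list was chosen in part on these arrays and is therefore not independent evidence of its direction. SOX4, a transcription factor of progenitor cells, had a signal of 3103 ± 162 (SD, n = 2) in control and 1153 ± 289 (SD, n = 2) in miR-335 cells, a log2 fold change of -1.43 ± 0.15 (SE) or 2.70-fold lower (adjusted p = 0.000524). Of its other probe sets past the filter, a pair was 3.81-fold and 2.99-fold lower, and a dim one was 1.14-fold lower and not called. MERTK, a receptor tyrosine kinase, went from 944 ± 130 to 366 ± 67.4, 2.50-fold lower (adjusted p = 0.000862). The matrix glycoprotein tenascin C (TNC) went from 1482 ± 7.72 to 979.9 ± 47.2, 1.5-fold lower (adjusted p = 0.00331), and the phospholipase PLCB1 from 1164 ± 0.141 to 769 ± 42.4, also 1.5-fold lower (adjusted p = 0.00462). For the phosphatase family member PTPRN2 the signals were 2309 ± 124 and 1756 ± 214, 1.31-fold lower (adjusted p = 0.0265), with its other probe sets 1.70-fold and 1.94-fold lower. The brightest probe set of the collagen gene COL1A1 read 7376 ± 533 and 6786 ± 68.9 and was not called (adjusted p = 0.405), while another of its probe sets read 1336 ± 11.6 and 847 ± 22.9, 1.56-fold lower (adjusted p = 0.00518). The brightest probe set of COL1A1 was called lower under quantile and cyclic loess normalization (adjusted p = 0.0122 and adjusted p = 0.0253), and its log2 fold change was 0.01 after median centring (adjusted p = 0.941). The list had a median log2 fold change of -0.58 and passed the list test (adjusted p = 0.00037; adjusted p = 0.367 with an estimated correlation). PTPRN2 was not called without control replicate B (adjusted p = 0.125), without miR-335 replicate A (adjusted p = 0.0689), after median centring (adjusted p = 0.106), without the level filter (adjusted p = 0.0627) or without the intensity trend (adjusted p = 0.124). PLCB1 was not called with the mean of its probe sets (adjusted p = 0.0683), and dimmer probe sets of PLCB1 and TNC were not called. MEST, the gene that hosts miR-335 in an intron, read 712 ± 19.5 and 684 ± 64.8, a difference within the spread between arrays (log2 fold change -0.06 ± 0.12, adjusted p = 0.779).

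**Figure D1:**
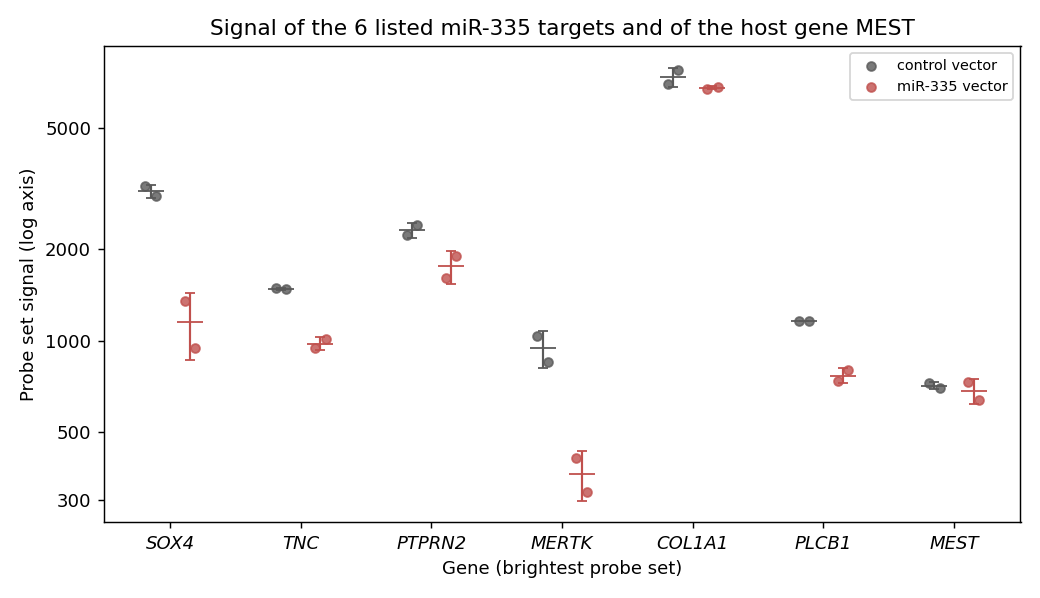
Signal of the brightest probe set of the 6 listed miR-335 targets and of MEST (log axis), with points for the 2 arrays of each group and bars for mean and SD. The miR-335 arrays lie below the control arrays for SOX4 (1357 and 949 against 3217 and 2989) and MERTK, and overlap with them for MEST.

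Among the largest rises with miR-335 was ID3, an inhibitor of basic helix-loop-helix transcription factors, which went from 156 ± 23.2 to 1150 ± 307, 6.50-fold higher (log2 fold change 2.70 ± 0.20, adjusted p = 0.000185). KISS1, which encodes the kisspeptin precursor and is known as a metastasis suppressor gene, went from 851 ± 279 to 2797 ± 613, 3.27-fold higher (adjusted p = 0.000808). FGF13, a fibroblast growth factor homologue that stays inside the cell, rose 3.06-fold, the cadherin family gene FAT3 2.79-fold, the ubiquitin hydrolase gene UCHL1 2.58-fold and GPATCH4 2.57-fold, from 1073 ± 67.0 to 2796 ± 141. The rise of UCHL1 was not seen by another of its probe sets, which read 147 and 137, and a dimmer probe set of FAT3 was not called. Another probe set of GPATCH4 also rose, from 934 to 2029, while a dim one read 153 and 111 and was not called. HBB, the beta-globin gene, rose 5.23-fold on 1 probe set, from 172 ± 35.0 to 991 ± 170, but others read 263 and 196 and 180 and 194, neither of them called. XIST, the long noncoding RNA of X inactivation, rose 2.86-fold (log2 fold change 1.51, adjusted p = 0.00355). Of its 5 other probe sets past the filter 3 were called higher, with log2 fold changes of 1.82 to 3.89, and 2 were not called. The control signals of the 3 called ones lie below the level of the Bacillus controls, so their sizes are uncertain. KIR2DL3, DEFB124 and CLDN16 rose 3.83-fold, 2.88-fold and 2.86-fold from control signals of 25, 74.5 and 50.7, which lie below the 77.6 of the Bacillus controls. The probe sets used for HBB, KIR2DL3, DEFB124 and XIST, and below for CXCL2, CXCL8, SLC2A3, HSP90B1, RET, RPL3, KRT8 and KRT18, may read other transcripts too, as their _x_at names denote. PRPF19, a splicing factor gene, rose 2.83-fold, but its control arrays read 747 and 2395: its log2 fold change of 1.5 was 0.67 without control replicate A and 2.33 without control replicate B. The call of PRPF19 was lost in a robust fit (adjusted p = 0.258) and without the level filter (adjusted p = 0.0982) or the intensity trend (adjusted p = 0.133). DEFB124 had a log2 fold change of 0.73 without miR-335 replicate B and was then not called (adjusted p = 0.128), and 2.32 without miR-335 replicate A. DEFB124 and CLDN16 were not called without the level filter (adjusted p = 0.113 and adjusted p = 0.0579) or the intensity trend (adjusted p = 0.124 and adjusted p = 0.0657). DEFB124 was not called in a robust fit (adjusted p = 0.0626) or with the mean of its probe sets (adjusted p = 0.053).

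Among the largest falls was that of AGR2, which encodes a protein disulfide isomerase of secretory epithelia, from 581 ± 4.0 to 80.5 ± 91.7 (log2 fold change -2.92 ± 0.53, adjusted p = 0.00397). The miR-335 arrays read 145 and 15.7 for AGR2, and the log2 fold change was -4.0 without miR-335 replicate A and -1.85 without miR-335 replicate B. The secreted cysteine protease inhibitors CST1 and CST4 were 5.16-fold and 4.29-fold lower, CST4 going from 2415 ± 297 to 548 ± 93.0 (adjusted p = 0.000185). These cystatin genes are close relatives, so their probe sets may read each other's transcripts. ICAM1, a cell adhesion molecule that binds leukocyte integrins, went from 1119 ± 71.0 to 267 ± 35.2, 3.96-fold lower (adjusted p = 0.000185), while another probe set was 2.12-fold lower and a dimmer one read 223 and 140 and was not called. The calcium channel subunit gene CACNG4 went from 844 ± 0.0354 to 206 ± 3.76, 3.80-fold lower. PNRC1, a nuclear receptor coactivator gene, was 4.16-fold lower, with 1087 and 292 on the miR-335 arrays and a log2 fold change of -2.06 that was -2.97 without miR-335 replicate A and -1.15 without miR-335 replicate B. PNRC1 and AGR2 were not called in a robust fit (adjusted p = 0.186 and adjusted p = 0.0511) or without the intensity trend (adjusted p = 0.088 and adjusted p = 0.0647). PNRC1 was also not called without the level filter (adjusted p = 0.0528). TEX26-AS1, RNF144A, PSG11, SLCO4C1, AATK and PRPF40B fell 3.82-fold to 4.93-fold to signals of 25.7 to 73.7, below the level of the Bacillus controls, so these folds understate the fall. PSG11 belongs to a family of near-identical genes and its identity is uncertain.

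**Figure D2:**
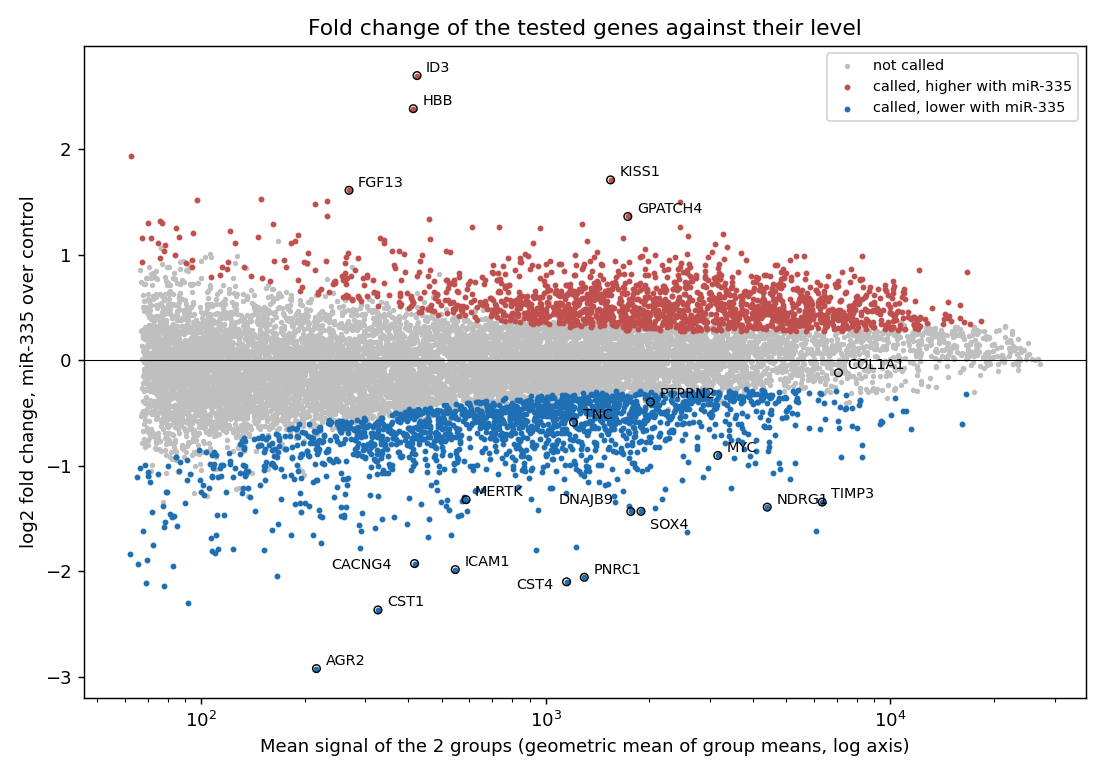
Log2 fold change of miR-335 over control for each of the 14086 tested genes (points) against the geometric mean of the group mean signals (log axis), with called genes in red (higher) and blue (lower). ID3 stands at 2.70 and AGR2 at -2.92, and the called changes narrow towards 0 as the signal grows.

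The cell cycle and respiration lists held rises and no falls. Among 40 tested cell cycle genes, 22 rose, 0 fell and 18 were not called (24 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 0.40. The list passed its test (adjusted p = 2.65e-09; adjusted p = 0.367 with an estimated correlation). CDC25A, a phosphatase that activates cyclin-dependent kinases, rose 2.23-fold from 303 ± 10.9 to 702 ± 7.20, the S-phase transcription factor E2F1 2.01-fold, the ribonucleotide reductase subunit RRM2 1.79-fold and the mitotic kinase AURKB 1.68-fold. The dimmer probe sets of CDC25A read 265 and 296 and 155 and 157, and another of E2F1 read 603 and 613, none of them called, nor was a dim one of AURKB, and CDC25A was not called with the mean of its probe sets (adjusted p = 0.0512). Oxidative phosphorylation genes showed 12 rises and 0 falls among 20 tested (16 rises when adjusted over the list alone), with a median of 0.37 (adjusted p = 8.98e-08; adjusted p = 0.367 with an estimated correlation). Under quantile normalization the medians of the cell cycle and oxidative phosphorylation lists were 0.22 and 0.23. The complex III subunit gene CYC1 rose 1.45-fold, from 6695 ± 292 to 9704 ± 265, and the complex I subunit gene NDUFS3 1.42-fold. Of the ribosomal protein genes 1 of 17 rose, RPS9 at 1.32-fold on its brightest probe set, and 0 did when adjusted over the list alone. Another probe set of RPS9, with an _x_at name, rose more, from 11810 to 18500 (log2 fold change 0.645, adjusted p = 0.00495). RPS9 was not called without control replicate A or B (adjusted p = 0.222 and adjusted p = 0.0627), without the level filter (adjusted p = 0.0593), without the intensity trend (adjusted p = 0.0943) or under cyclic loess normalization (adjusted p = 0.0745). RPL8, RPL3 and RPL6 had log2 fold changes of 0.31, 0.29 and 0.32 and were not called. They were called after median centring (adjusted p = 0.0127, adjusted p = 0.0137 and adjusted p = 0.0189). RPL8 and RPL6 were also called under quantile normalization (adjusted p = 0.0233 and adjusted p = 0.00694) and without miR-335 replicate A (adjusted p = 0.0399 and adjusted p = 0.0179). The ribosomal list had a median of 0.13 and passed its test (adjusted p = 0.0201; adjusted p = 0.796 with an estimated correlation), but the median turned to -0.14 under cyclic loess normalization (adjusted p = 0.00605) and to -0.015 without miR-335 replicate B (adjusted p = 0.473). The list did not pass without control replicate A (adjusted p = 0.474), under quantile normalization (adjusted p = 0.202) or with a stricter level filter (adjusted p = 0.075).

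In the list of the unfolded protein response and amino acid stress 13 of 20 genes fell and 0 rose (15 fell when adjusted over the list alone), with a median log2 fold change of -0.73 (adjusted p = 8.98e-08; adjusted p = 0.367 with an estimated correlation). DNAJB9, a chaperone of the endoplasmic reticulum, went from 2922 ± 217 to 1068 ± 71.1, 2.70-fold lower. The pseudokinase gene TRIB3 was 2.18-fold, HERPUD1 of the degradation pathway of the endoplasmic reticulum 1.96-fold and the chaperone gene HSP90B1 1.82-fold lower. Of 15 cholesterol synthesis genes 11 fell and 0 rose (13 fell when adjusted over the list alone), with a median of -0.69 (adjusted p = 2.47e-07; adjusted p = 0.367 with an estimated correlation). The sterol enzyme genes MSMO1, DHCR7 and LSS were 2.18-fold, 2.07-fold and 1.99-fold lower, LSS going from 5447 ± 151 to 2738 ± 255, and the sterol carrier gene STARD4 was 1.62-fold lower. Among 19 immediate early genes 8 fell and 0 rose (11 fell when adjusted over the list alone), with a median of -0.48 (adjusted p = 0.000112; adjusted p = 0.367 with an estimated correlation). The growth factor response genes DUSP5, DUSP6, MYC and KLF6 were 2.03-fold, 1.89-fold, 1.87-fold and 1.54-fold lower, with DUSP6 at 9899 ± 171 in control and 5233 ± 46.6 in miR-335 cells. Of the other probe sets of KLF6, 1 was 1.82-fold lower and 3 were not called. Another probe set of LSS was 2.43-fold lower, and a dimmer one of LSS and of HSP90B1 were not called.

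Of 15 tested epithelial markers, 8 fell and 0 rose (9 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of -0.56 (adjusted p = 0.00037; adjusted p = 0.367 with an estimated correlation). KRT19, a keratin, went from 4526 ± 71.1 to 1464 ± 304, 3.09-fold lower. The junction genes JUP, CLDN7 and CLDN4 were 3.20-fold, 2.69-fold and 3.55-fold lower, CLDN4 ending at a dim 51.6. KRT18, KRT8, EPCAM and KRT7, looked at after the results were seen, had log2 fold changes of 0.25, 0.01, 0.11 and -0.21 and were not called. Of the 7 members not called these were the highest. Integrins and other adhesion genes showed 8 falls and 1 rise among 22 (9 falls and 1 rise when adjusted over the list alone), with a median of -0.22 (adjusted p = 0.00388; adjusted p = 0.367 with an estimated correlation). Besides ICAM1, the integrin chains ITGA1, ITGA2 and ITGB4 fell, by 2.57-fold, 1.90-fold and 1.88-fold, ITGB4 by 3.66-fold and 2.43-fold on other probe sets. NF-kB targets and cytokines had 10 falls and 1 rise among 21 (11 falls and 1 rise when adjusted over the list alone), with a median of -0.60 (adjusted p = 0.00101; adjusted p = 0.531 with an estimated correlation). Without miR-335 replicate B the median was -0.30 (adjusted p = 0.0122). The macrophage growth factor CSF1 and the chemokines CXCL2 and CXCL8 were 2.06-fold, 2.22-fold and 1.69-fold lower, and other probe sets of CSF1 2.13-fold and 3.73-fold. Another probe set of ITGA1 was 2.58-fold lower, and the dimmest past the filter of ITGA1 and of CSF1 were not called.

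Receptor kinases and phosphatases fell in 11 of 21 cases and rose in 0 (11 falls and 1 rise when adjusted over the list alone), with a median log2 fold change of -0.35 (adjusted p = 0.00205; adjusted p = 0.367 with an estimated correlation). PTPRG was 1.92-fold and IGF1R 1.68-fold lower on their brightest probe sets, with 1 dimmer probe set of each also called lower and the others not called, and RET was 3.49-fold lower to a dim 76.7. IGF1R was not called with the mean of its probe sets (adjusted p = 0.0516). The receptor list also holds MERTK and PTPRN2, listed miR-335 targets chosen in part on these arrays, so its test is not fully independent of them. Hypoxia response genes fell in 9 of 22 cases and rose in 1 (10 falls and 1 rise when adjusted over the list alone), with a median of -0.29 (adjusted p = 0.00306; adjusted p = 0.441 with an estimated correlation). NDRG1, a stress and differentiation gene, went from 7141 ± 382 to 2707 ± 168, 2.63-fold lower, the glucose transporter gene SLC2A3 was 2.06-fold and the collagen hydroxylase gene P4HA1 1.66-fold lower, while ADM, the gene of the peptide hormone adrenomedullin, rose 1.99-fold. SOX, FOX and HOX factors fell in 5 of 14 cases (6 when adjusted over the list alone) and rose in 0, with a median of -0.18 (adjusted p = 0.0259; adjusted p = 0.367 with an estimated correlation; adjusted p = 0.106 without the level filter). The median was -0.61 with a stricter level filter (adjusted p = 0.00167) and -0.05 after median centring (adjusted p = 0.0129). Besides SOX4, FOXQ1 was 2.04-fold and SOX9 1.52-fold lower. SOX4 is a listed miR-335 target too, so the same limit holds for the list of SOX, FOX and HOX factors. Interferon response genes had 5 falls and 2 rises among 28 (6 falls and 2 rises when adjusted over the list alone), with a median of -0.24 (adjusted p = 0.0426; adjusted p = 0.367 with an estimated correlation). The share called was near the 23.9% of all tested genes. The interferon list did not pass under quantile normalization (adjusted p = 0.111), cyclic loess normalization (adjusted p = 0.0998), other level filters (adjusted p = 0.0643 and 0.0585), or without control replicate B or miR-335 replicate B (adjusted p = 0.131 and 0.137). Its membrane protein gene IFITM1 went from 2483 ± 53.8 to 1010 ± 167, 2.44-fold lower, and the signalling factor gene IRF9 was 1.67-fold lower.

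**Figure D3:**
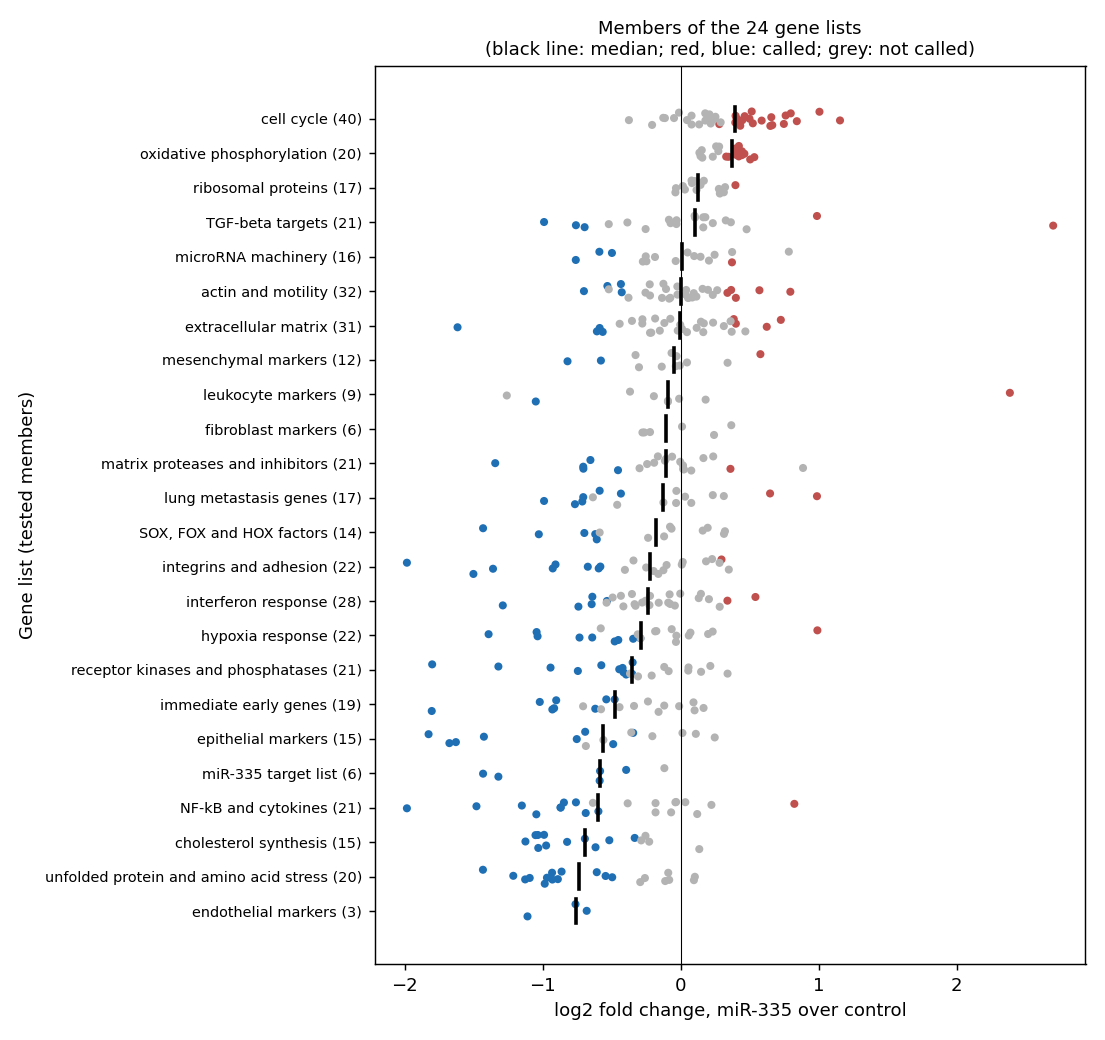
Log2 fold change of miR-335 over control for each tested member (points) of the 24 gene lists, with the number of tested members in parentheses and the list median as a black line. Medians run from -0.76 for the 3 endothelial markers to 0.40 for the 40 cell cycle genes, and the points of the lists near 0 spread to both sides.

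Several groups named for invasion and matrix did not pass the list test, although single members changed. Over all tested genes 23.9% were called. The shares called in the extracellular matrix, mesenchymal, TGF-beta, actin and microRNA lists lay near this. Lung metastasis genes had 2 rises and 6 falls among 17 (3 and 7 when adjusted over the list alone), with a median log2 fold change of -0.12 (adjusted p = 0.203), and passed only without miR-335 replicate A (median -0.39, adjusted p = 0.0376). Its median was -0.03 without miR-335 replicate B and 0.006 after median centring. Median centring shifted all tested genes alike, here and for the lists below. ID1 rose 1.98-fold and the decoy receptor gene IL13RA2 1.57-fold, while LTBP1, which binds latent TGF-beta, was 1.99-fold and the growth factor gene EREG 1.64-fold lower. Another probe set of LTBP1 was 8.83-fold lower, from 324 to a dim 16.8 (adjusted p = 0.001). A second probe set each of EREG and COL7A1 was not called. Other probe sets of ZEB1 were 1.80-fold and 1.75-fold lower and a dim one was not called. Matrix proteases and inhibitors had 1 rise and 5 falls among 21 (2 and 6 when adjusted over the list alone; median -0.11, adjusted p = 0.112), and passed under quantile normalization (adjusted p = 0.00136), under cyclic loess normalization (adjusted p = 0.00301) and without control replicate A (adjusted p = 0.0204). The median of this list was 0.002 without miR-335 replicate A, -0.21 without miR-335 replicate B and 0.025 after median centring. TIMP3, an inhibitor of metalloproteases, went from 10130 ± 657 to 3977 ± 296, 2.54-fold lower, and MMP2, PLAT and CTSD were 1.63-fold, 1.63-fold and 1.57-fold lower. Extracellular matrix genes had 4 rises and 4 falls among 31, the same counts as when adjusted over the list alone (median -0.003, adjusted p = 0.963), with HSPG2, the gene of perlecan, 3.07-fold lower and the collagen gene COL7A1 1.65-fold higher. Without miR-335 replicate A the median of this list was 0.20 (adjusted p = 0.0334). Among mesenchymal markers LOX and ZEB1 were 1.77-fold and 1.49-fold lower and SNAI2 rose 1.49-fold, 3 calls among 12 (4 when adjusted over the list alone, of which 2 rose), with adjusted p = 0.664 for the list, and AXL had a log2 fold change of 0.34 and was not called. AXL was called after median centring (adjusted p = 0.0139) and without miR-335 replicate A (adjusted p = 0.00713). TGF-beta targets had 2 rises, ID3 and ID1, and 3 falls, of which LTBP1 and TGFBR2 (1.69-fold lower, 2.59-fold on another probe set) had the smallest p, among 21 (2 and 4 when adjusted over the list alone; adjusted p = 0.775). Actin and motility genes had 5 rises and 4 falls among 32 (6 and 4 when adjusted over the list alone; adjusted p = 0.791), TPM1 rising 1.49-fold and RHOB being 1.63-fold lower, and TPM1 was not called with the mean of its probe sets (adjusted p = 0.735). Other probe sets of TPM1 rose, with log2 fold changes of 0.50 and 0.45 (adjusted p = 0.0192 and adjusted p = 0.029). A dim one read 161 and 70.5 and was not called. Genes of the microRNA machinery had 1 rise and 3 falls among 16, alike when adjusted over the list alone (adjusted p = 0.972), with the Argonaute gene AGO4 1.69-fold and the helicase gene DDX5 1.5-fold lower. AGO4 was not called with the mean of its probe sets (adjusted p = 0.0526). DDX5 was not called without control replicate B (adjusted p = 0.135), under quantile normalization (adjusted p = 0.0568), without the level filter (adjusted p = 0.0516) or without the intensity trend (adjusted p = 0.0876). The mean and the median differed in sign for the actin and microRNA lists, and the direction of the test and the median for the matrix and microRNA lists.

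Markers of cell types other than the cancer cells were also compared. All 3 tested endothelial markers of 10 fell, also when adjusted over the list alone: ESAM went from 1690 ± 101 to 1045 ± 2.92, PECAM1 from 674 ± 13.3 to 389 ± 29.5 and KDR from 171 ± 17.4 to a dim 67.5 ± 8.07, 1.60-fold, 1.70-fold and 2.16-fold lower (list median -0.76, adjusted p = 0.00564; adjusted p = 0.367 with an estimated correlation). KDR was not called without control replicate A (adjusted p = 0.0661). Of 9 markers of leukocytes and red cells, HBB rose and CD14 fell, from 206 ± 9.95 to 88.4 ± 7.29 (1 rise and 2 falls when adjusted over the list alone, adjusted p = 0.891), while CD8A and CSF1R had log2 fold changes of -1.26 and -0.37 and were not called. CD8A was called with a higher pseudocount (adjusted p = 0.0468). Its log2 fold change was -1.563 without control replicate B and -1.915 without miR-335 replicate B. Fibroblast markers had 0 calls among 6 in limma, also when adjusted over the list alone, with adjusted p = 0.901 for the list and log2 fold changes of -0.28 for COL1A2, -0.26 for CXCL12, -0.22 for FBLN1 and 0.24 for MFAP5. Another probe set of FBLN1 was 1.77-fold lower, from 414 to 225 (adjusted p = 0.011). Of the 24 lists 15 passed, 3 upwards and 12 downwards. These are not separate results: some lists share genes, such as ICAM1, and the target list was chosen in part on these arrays. With an estimated correlation, which rests on 2 arrays per group, 0 passed (lowest adjusted p = 0.367) and 1, oxidative phosphorylation, had an unadjusted p in camera under 0.05.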

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

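Cyclic loess normalization was chosen after seeing the data. The gene count of 3366 stayed within 1.5 times under quantile normalization (3229), median centring (3608), cyclic loess normalization (3189) and all level filters and pseudocounts tried, but was 1157 without the intensity trend, whose prior had 3.01 instead of 7.68 degrees of freedom. Leaving out each array gave 2128 to 3780 calls. Of the 3366 calls, 78.7% stayed called in the same direction under quantile normalization, 79.1% under median centring, 80.2% under cyclic loess normalization, 68.2% without the level filter, 70.6% with the mean of a gene's probe sets and 33.1% without the trend. The single probe sets gave 5796 calls of 32768 (2333 higher, 3463 lower; 3764 higher, 2068 lower after median centring), 3159 without the level filter, 1 without the trend and 3525 to 6317 without an array. The all-pairs count at 1.5-fold was 849 (302 higher, 547 lower), 925 after median centring (590 higher, 335 lower), 118 at 2-fold by its construction, and 1321 to 1638 without an array, because fewer pairs must then pass. The balance of rises and falls in all 3 counts thus depends on the scaling. The other splits of the 4 arrays into pairs, A against B and crossed, gave 33 and 38 genes at 1.5-fold. With 3 splits no share under 0.05 can be reached.

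The 15 lists past the test became 0 with an estimated correlation, and 13 to 17 without an array. The list of miR-335 targets kept its median of -0.58 there but not its call (adjusted p = 0.367, the highest over 14 alternatives, the lowest being 1.83e-05), where the correlation between genes is all that changes. The ribosomal protein list turned to -0.14 under cyclic loess normalization and ranged from -0.015 to 0.27 without an array, and extracellular matrix from -0.21 to 0.20; the cause was not tested. After median centring the medians of the integrin, hypoxia, receptor kinase and interferon lists were -0.09, -0.16, -0.22 and -0.11. The median of all tested genes was then 0.09, and these lists still passed (adjusted p = 0.00333, 0.00504, 0.00216 and 0.0491 in camera). Of the called named genes 0 changed sign under any alternative, and of those not called 4 did, with COL1A1 at 0.01 after median centring. The trend-free prior ended the most calls of named genes (26, among them CTSD, TPM1, RHOB, SNAI2, IRF9, CXCL8, RET, CYC1 and NDUFS3), followed by the analysis without a level filter (11). The replicate letters share no stated culture or day, and deviations from the group means of same-lettered arrays had r = -0.03 across genes. With the replicate block there were 3779 gene calls, 97.5% of the 3366 among them, 6334 probe set calls and 14 lists, the interferon list being lost (adjusted p = 0.0559). Among the named genes the block added the calls of RPL8, RPL3, RPL6 and AXL upwards and of CD8A downwards (adjusted p = 0.000804, 0.00338, 0.000694, 0.00136 and 0.0193). The search for miR-335 seed sites was not run. Of the called genes, 88 had a group below the level of the Bacillus controls, where signal over background limits the fold.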

Other observations

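The gene lists of the next paragraph, and the tests below except that on growth state, were chosen after the results were seen.

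Genes of ribosome biogenesis, which make and assemble ribosomal subunits in the nucleolus, formed a group not covered above. Of 40 tested, 31 rose and 0 fell (33 rose when adjusted over the list alone), with a median log2 fold change of 0.60 (adjusted p = 4.85e-21 in camera; adjusted p = 0.0311 with an estimated correlation). These p-values are adjusted over the 4 added lists, and over all 28 lists the list did not pass with an estimated correlation (adjusted p = 0.217). The list was prompted by GPATCH4, RRS1, MRTO4 and RRP9 in these data. Its p-values, also those without these genes, are therefore not independent evidence. GPATCH4 rose 2.57-fold, RRS1 2.45-fold from 807 to 2006, MRTO4 2.41-fold and NOP16 1.97-fold. Without GPATCH4, RRS1, MRTO4 and RRP9, 27 of 36 rose (median 0.55; adjusted p = 0.0384 with an estimated correlation, adjusted p = 0.269 over 28 lists). Over 16 alternatives the median lay between 0.51 and 0.73 and 18 to 34 members rose. Of the 40, 0 stand in another list. Chaperones of the endoplasmic reticulum had 8 falls and 0 rises among 15 (9 falls when adjusted over the list alone), with a median of -0.50 (adjusted p = 1.49e-05; adjusted p = 0.201 with an estimated correlation), HYOU1 falling 1.82-fold and PDIA4 2.13-fold. Targets of the transcription factor ATF4 had 11 falls and 1 rise among 21 (14 falls and 1 rise when adjusted over the list alone), with a median of -0.50 (adjusted p = 2.86e-05; adjusted p = 0.216 with an estimated correlation), GDF15 falling 3.47-fold and DDIT3 2.32-fold. Of these lists 4 chaperones and 12 ATF4 targets, among them PDIA4 and DDIT3, also stand in earlier lists. Of the other 11 chaperones 4 fell and 0 rose, and of the other 9 ATF4 targets 3 fell and 1 rose. The medians of these other members were -0.23 and -0.16. Both lists were chosen after the results were seen, so their p-values are not independent evidence either. The tRNA synthetases had 4 rises and 2 falls among 15 (4 and 4 when adjusted over the list alone; adjusted p = 0.422), with RARS1 1.65-fold higher, and their median of 0.005 turned to -0.15 under quantile normalization.

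The first pattern weighed was the 3366 calls themselves. Uneven scaling as their whole cause is argued against by the 78.7% of calls kept in the same direction under quantile normalization. It may still account for part of them, since the balance of rises and falls depended on the scaling. The different labelling text of control replicate A as their whole cause is argued against by control replicate B. Over all tested genes it differed from the nearer miR-335 array by a median log2 size of 0.272, where arrays of a group differed by at most 0.164. The labelling may still account for part of the calls. A separate hybridization or reagent lot for each group cannot be told apart from the vector: bioC differed by -0.97 on the log2 scale, more than within the groups, while the other 3 spike-ins did not, and no label gives a lot. An effect of miR-335 and a difference between the cells that received the vectors, both untested, remain open.

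The second pattern was the rise of cell cycle and respiration genes with the fall of stress and sterol genes. A bias that depends on the signal level, as the whole cause, is argued against by cyclic loess normalization, after which the cell cycle median was 0.23 ± 0.07 (SE of the median over genes, adjusted p = 3.26e-06) and that of respiration 0.23 ± 0.05 (adjusted p = 0.00147), although only 56.7% and 63.0% of their size was kept. Such errors and p-values take the genes of a list as nearly independent, and no estimated correlation was used after this normalization. Over 14 alternatives the adjusted p of these lists ran from 7.24e-12 and 1.65e-09 to 0.367, the last with an estimated correlation. The stress and cholesterol lists kept 103.6% and 105.9%, the latter at -0.74 ± 0.13. A different growth state of the cultures, such as density or time since feeding, may account for the pattern and cannot be told apart from the vector: list means varied within a vector by at most 0.353 of their difference between vectors, and the labels do not say that cultures were matched. An effect of miR-335 on growth, also untested, remains open.

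The third pattern was the higher HBB signal. RNA of red blood cell precursors as its source is argued against by the other 3 HBB and the 6 alpha-globin probe sets, whose median log2 fold change was 0.093 ± 0.17 (SE) and whose alpha-globin signals reached at most 139 with miR-335. This error takes the probe sets as independent, although those for alpha-globin read the same genes. Several of these probe sets lie below the level filter, where the pseudocount shrinks a rise. Those past the filter had log2 fold changes from -0.375 to 0.416. The delta-globin gene HBD, described below, goes the other way. A sequence seen by a single HBB probe set is a possible explanation that stays open, because a dim HBB probe set, at 10.9 and 39.6, also differed by 0.88, and the delta-globin gene HBD, below the level filter, read 35.4 and 110.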
